A study of Homo sapiens
Mus musculus with 64 samples.

How the data were processed

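Messenger RNA of 64 MCF7 xenograft tumours was sequenced by the authors from stranded mRNA libraries, per the labels' protocols. The deposited values were raw counts, whole numbers for 57373 Ensembl gene rows and 92 spike-in rows, 1 column per tumour. Reads were trimmed with cutadapt 1.12, checked with FastQC 0.11.5 and aligned with STAR 2.5.3a, and GRCh37 was the build, per the submitters' processing notes, which name these tools and the build without a role or an order. The counting tool, its strand setting, the annotation release and the treatment of reads from mouse cells in the tumours are not given in the sources used here. Counts of genes that overlap, lie antisense to one another or have near-identical copies are therefore uncertain. The table held no mouse genes, so the mouse part of the tumours was not analysed here. Spike-in rows were kept out of library sizes and tests, and made up 0.186% to 0.789% of a tumour's counts.

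The mouse was taken as the replicate, because it received the drug. The number in a title was read as the mouse and the letter as the flank. Counts were summed over the tumours of a mouse, and 2 of the 33 mice, both given palbociclib, had 1 tumour. The flanks of a mouse were only weakly alike. Each tumour's deviation was taken from the mean of the other mice of its group. The median correlation of these deviations was 0.244 within a mouse (lowest -0.314) and -0.211 between mice of a group. Flanks of a mouse share the mean subtracted, which by itself gives positive values. Between mice, centring small groups itself gives negative values. The consensus correlation within a mouse was 0.172, and 10 of 62 tumours had their partner as the best match. None of 260 pairs of tumours within a group was identical, and the lowest chi-square per degree of freedom was 2.24 over genes with at least 10 counts in a pair.

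All 33 mice of the 8 groups entered a single fit in edgeR 4.0.16 (R 4.3.3, limma 3.58.1), with filterByExpr, TMM scaling and the quasi-likelihood F test, two-sided. P-values were adjusted by Benjamini-Hochberg over 15918 genes with a threshold of 0.05 and no fold limit. The biological coefficient of variation was 0.195. The dose trend was fitted on the 15 abemaciclib mice against log2 dose. Log2 values per mouse used a prior count of 2. Standard errors were derived from the fold change and its F value. Score differences were tested by exact permutation of mice, two-sided, with 95% intervals from the pooled spread, and adjusted over 40 tests. Correlations with dose used 100000 permutations. No batch was given in the labels. Mice were the replicates in all tests, but whether the animals were handled or sequenced in batches is not given in the sources used here.

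The 36 gene lists of 678 symbols fixed before the data were examined, among them cell type markers, and the rule that named genes by symbol could not be applied. The table has no symbols, and 0 of its 57373 IDs matched the name table used here. The rule took the 10 largest rises and falls per comparison among genes past the threshold, with a mean count of at least 100 per mouse and every mouse of one group beyond every mouse of the other. Its conditions were kept for IDs without the limit of 10, and at most 2 rising and 2 falling IDs are printed. In place of the symbol lists, cell cycle IDs were taken from the marker pairs that ship with scran 1.30.0, made from sorted human embryonic stem cells. The cell cycle list holds every ID in those pairs. A phase list holds IDs that stand in at least 20 pairs and first in at least 90% of them. This rule was chosen after the data were examined, when list tests with minimums of 10 or 20 pairs and 80% or 90% had been seen. The 3 phase lists share 6 to 11 IDs with one another. Enrichment was tested by Fisher's exact test against all genes tested, and lists by camera with a preset correlation of 0.01, with an estimated correlation and fry as alternatives.

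The fits were tested on simulated counts with the means, library sizes and dispersions of the real mice and 67, 67 and 66 genes per drug group changed 1.5-fold, 2-fold and 4-fold. Changed genes were placed only among genes above a minimum mean count, rises and falls were balanced, and genes were drawn independently. Recovery and false calls may therefore be worse in the real data, above all for genes with few counts. In palbociclib against vehicle, edgeR called 98.5% of 4-fold, 89.6% of 2-fold and 47.8% of 1.5-fold changes of 15906 genes, and 4.27% of its calls were false. DESeq2 called 98.5%, 92.5% and 59.7% there, and 9.73% of its calls were false. In abemaciclib at 25 mg/kg against vehicle, edgeR called 100% of 4-fold, 77.6% of 2-fold and 23.9% of 1.5-fold changes, and 5.63% of its calls were false. In the dose trend, 97.0% of slopes of 0.6 and 44.8% of slopes of 0.3 were called of 15728 genes. Alternatives fixed beforehand were DESeq2 1.42.0, other size factors, library size alone, other filters, tumours as samples with and without the mouse as a block, single flanks, smaller fits, a fold limit of 1.5 by glmTreat, other dose scales and each mouse left out. Scaling by spike-ins, a residual component as a covariate, leaving out mice with 1 tumour, pooling 3 abemaciclib doses and phase lists at 10 pairs and 80% were added after the data were examined.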

Results

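RNA was sequenced from tumours that MCF7 cells had formed in nude mice. MCF7 is a human breast cancer cell line that carries the oestrogen receptor, and the animals were given oestradiol. The mice carried a tumour in each flank and received vehicle, ribociclib, palbociclib or abemaciclib daily for 4 days. Tumours were taken 2 hours after the last dose. All 3 drugs are inhibitors of the cyclin-dependent kinases CDK4 and CDK6, which drive cells from the first gap phase of the cell cycle into DNA synthesis. Palbociclib is built on a pyridopyrimidinone, ribociclib on a pyrrolopyrimidine and abemaciclib on a pyrimidine that bears a fluorinated benzimidazole. The deposited table held raw counts for 64 tumours. The number in a tumour's title was read as its mouse and the letter as its flank, and counts were summed per mouse, which gave 33 mice. There were 7 vehicle mice, 6 given ribociclib at 150 mg/kg, 5 given palbociclib at 150 mg/kg and 3 at each abemaciclib dose of 25, 75, 100, 125 and 150 mg/kg. A tumour had between 1955970 and 4256512 gene counts, with a median of 2950380, and a mouse had between 2672628 and 7687793. The lowest of these mouse totals came from a palbociclib mouse with 1 tumour. With this depth 15918 genes could be tested, and they held 99.7% of the counts.

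The table identified genes by Ensembl IDs without symbols, so genes are described as groups. The main group, called the cell cycle list, holds every ID in a set of marker pairs for cell cycle phases. It was not taken from an annotation and need not hold every cell cycle gene. The list has 1314 Ensembl IDs, of which 1192 could be tested. Within it, 203 tested IDs were ranked high in the first gap phase (G1-high), 189 in DNA synthesis (S-high) and 174 in the second gap phase and mitosis (G2/M-high), by an independent ranking in sorted human embryonic stem cells. These lists were chosen after the data were examined. A list score is the mean log2 CPM (counts scaled by library size) of the list in a mouse less the mean of the vehicle mice.

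The first question was what each drug changed at the matched dose of 150 mg/kg. With palbociclib 397 of the 1192 cell cycle genes tested fell, 37 rose and 758 did not pass the test. The cell cycle score was -0.51 ± 0.064 (SD, n = 5) against 0 ± 0.078 (SD, n = 7) in vehicle, and every palbociclib mouse lay below every vehicle mouse (exact permutation test, two-sided, p = 0.00126, the smallest possible, and adjusted p = 0.00632 over 40 score tests). The G2/M-high genes had the lowest score, -0.96 ± 0.12, with 72 of 174 members lower and 4 higher. The G1-high score was -0.67 ± 0.045, with 77 of 203 members lower and 4 higher. The S-high score was -0.55 ± 0.073, with 74 of 189 members lower and 4 higher. The G1-high genes therefore fell too, although the name of the list refers to the phase in which their transcripts ranked high in stem cells. That ranking is relative within pairs of genes, and the G1-high list shares 11 IDs with the G2/M-high list. Membership therefore does not show that a gene is expressed mainly in the first gap phase in these tumours. Over all genes, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05 called 2854 changed, 1349 higher and 1505 lower. The balance of directions depended on the scaling: with spike-ins, chosen after the data were examined, palbociclib 150 vs vehicle had 113 higher and 678 lower. Cell cycle IDs made up 26.4% of the lowered genes and 64.3% of the 182 genes that fell at least 4-fold, against 7.49% of all tested genes. They made up 2.74% of the raised genes.

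**Figure D1:**
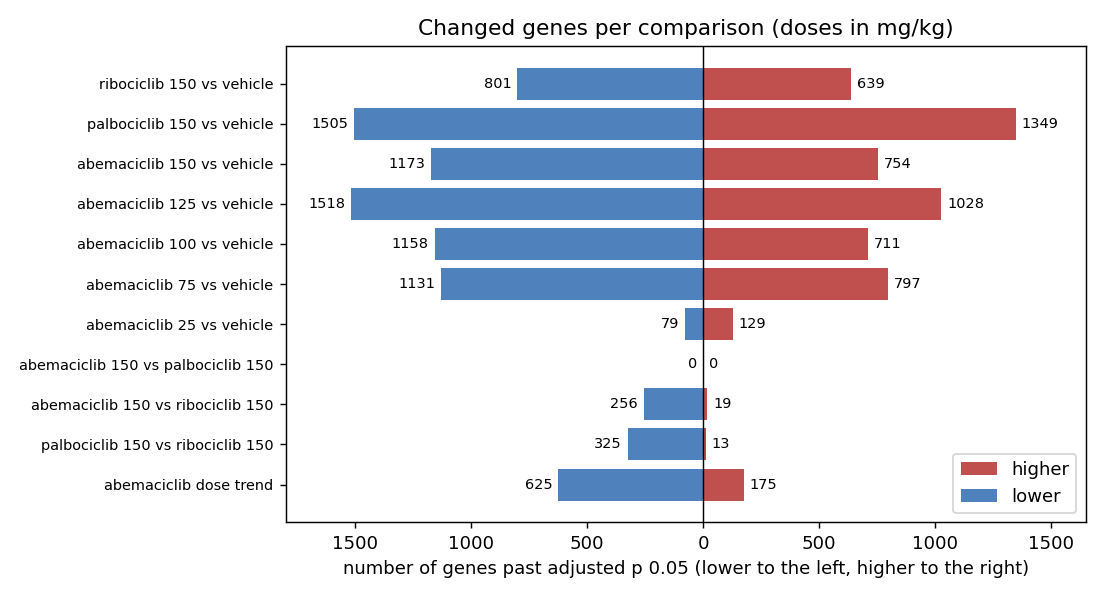
Number of genes past an adjusted p of 0.05 in each comparison, lower to the left and higher to the right on the horizontal axis, with doses in mg/kg. Palbociclib changed 2854 genes and abemaciclib at 25 mg/kg changed 208, and no gene differed between abemaciclib and palbociclib at 150 mg/kg.

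Abemaciclib at 150 mg/kg lowered 336 of the 1192 cell cycle genes and raised 31. Its cell cycle score was -0.49 ± 0.017 (SD, n = 3), below every vehicle mouse (exact permutation test, p = 0.00833, the smallest possible, adjusted p = 0.0124). The G2/M-high score was -0.92 ± 0.051, the G1-high score -0.63 ± 0.028 and the S-high score -0.55 ± 0.038. In these lists 68 of 174, 66 of 203 and 69 of 189 members fell, and 6, 4 and 1 rose. In all, 1927 genes changed, 754 higher and 1173 lower (31 and 490 with spike-in scaling), and cell cycle IDs were 28.6% of the lowered genes and 60.8% of the 204 that fell at least 4-fold. For abemaciclib 150 vs vehicle the count of changed genes was 1161 without mouse 46 and 1175 without mouse 43.

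Ribociclib at 150 mg/kg lowered 278 of the 1192 cell cycle genes and raised 25. The cell cycle score was -0.21 ± 0.038 (SD, n = 6), below every vehicle mouse (exact permutation test, p = 0.00117, adjusted p = 0.00632). The G2/M-high score was -0.37 ± 0.072, the G1-high score -0.28 ± 0.037 and the S-high score -0.25 ± 0.042. In these lists 59 of 174, 57 of 203 and 54 of 189 members fell, and 3, 5 and 1 rose. For ribociclib 150 vs vehicle there were 1440 changed genes, 639 higher and 801 lower (33 and 204 with spike-in scaling, 173 and 373 in right tumours alone). Cell cycle IDs were 34.7% of the lowered genes. A fall of at least 4-fold was called for 1 gene, against 182 with palbociclib. In the fit limited to ribociclib and vehicle the count of changed genes was 899, 313 higher and 586 lower.

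The set test (camera, preset inter-gene correlation of 0.01) called all 4 lists lower with each drug at 150 mg/kg, with adjusted p between 4.86e-38 and 3.36e-14. All of these calls held with an estimated correlation, the highest adjusted p being 0.00154 for the G2/M-high list with ribociclib. Of genes changed by each pair of drugs, 1183 were shared by ribociclib and palbociclib, 1075 by ribociclib and abemaciclib and 1525 by palbociclib and abemaciclib, and 0 went in opposite directions. A fall with all 3 drugs was called for 669 genes, 270 of them cell cycle IDs, and a rise for 320. These comparisons used the same vehicle mice. For ribociclib and palbociclib, 480 genes rose and 703 fell in both, where independent lists would share 54.2 and 75.7. Unchanged groups simulated against the same vehicle mice shared 0. That simulation held no effect and drew genes independently, so few calls could arise and the 0 sets no chance level. The correlation of the ribociclib and palbociclib fold changes across genes was 0.80 against 0.436 simulated, and the covariance 0.186 against 0.0258. For ribociclib and abemaciclib, 376 rose and 699 fell in both against 30.3 and 59.0 for independent lists, the correlation was 0.781 against 0.369 simulated, and the covariance was 0.182 against 0.0256. For palbociclib and abemaciclib, 533 rose and 992 fell in both against 63.9 and 111 for independent lists, the correlation was 0.866 against 0.343 simulated, and the covariance was 0.294 against 0.0255. With the vehicle mice split 4 and 3 between the comparisons, the median correlation over 35 splits was 0.621, 0.586 and 0.729 for the same 3 pairs. Genes are not independent replicates in these correlations.

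Single genes are given by ID only, because the files do not pair IDs with names. The 4 shown met the rule for named genes with all 3 drugs at 150 mg/kg, as did 54 raised and 257 lowered genes, and had the largest mean changes. Membership of a phase list does not show in which phase a gene is mainly expressed in these tumours. ENSG00000178999, a member of the G1-high list, averaged 6.47 ± 0.29 log2 CPM in vehicle (SD, n = 7). It was 29.2-fold lower with palbociclib (log2 -4.87, SE 0.36, edgeR adjusted p = 4.58e-12), 28.7-fold lower with abemaciclib at 150 mg/kg (log2 -4.85, SE 0.44) and 3.26-fold lower with ribociclib (log2 -1.70, SE 0.26, adjusted p = 3.01e-05). ENSG00000171848, a member of the S-high list, was 23.2-fold lower with palbociclib (log2 -4.54, SE 0.34), 29.3-fold lower with abemaciclib (log2 -4.87, SE 0.43) and 3.09-fold lower with ribociclib (log2 -1.63, SE 0.26). ENSG00000163141 was 2.04-fold higher with ribociclib, 2.70-fold higher with palbociclib and 2.19-fold higher with abemaciclib. ENSG00000105974 was 2.27-fold, 2.32-fold and 2.12-fold higher in the same order, and its call with abemaciclib was lost without mouse 46 (log2 0.75, edgeR adjusted p = 0.116).

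The drugs were then compared directly at 150 mg/kg. Palbociclib left the cell cycle genes lower than ribociclib did: 189 of 1192 were lower and 1 was higher. The cell cycle score differed by -0.30 (95% interval -0.37 to -0.23, exact permutation test, p = 0.00216, the smallest possible, adjusted p = 0.00722, n = 5 and 6), and no mouse of one group overlapped the other. For the G2/M-high list the difference was -0.59 (-0.72 to -0.46). Of the 338 genes that differed, 325 were lower with palbociclib, and 58.2% of these were cell cycle IDs. Abemaciclib also left these genes lower than ribociclib did, with 163 of 1192 lower and 1 higher. The score differed by -0.28 (-0.34 to -0.23, exact permutation test, p = 0.0119, the smallest possible, adjusted p = 0.0153, n = 3 and 6), and the G2/M-high score by -0.55 (-0.66 to -0.44). Of the 275 genes that differed, 256 were lower with abemaciclib. All 4 lists were lower than with ribociclib in both comparisons, and these calls held with an estimated correlation. The count for abemaciclib was 166 without mouse 46 and 173 without mouse 43.

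The gap between ribociclib and palbociclib widened with the size of the fall. Cell cycle genes that fell by less than 1 log2 unit with palbociclib had a median of -0.54 there and -0.26 with ribociclib (187 genes). The 24 that fell by more than 4 log2 units had a median of -4.37 with palbociclib and -1.61 with ribociclib, and none of the 24 lay below -1.85 with ribociclib. With abemaciclib at 150 mg/kg the median of the same 24 genes was -4.30. Genes were sorted by their palbociclib value, which by itself draws the most extreme values of that drug.

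**Figure D2:**
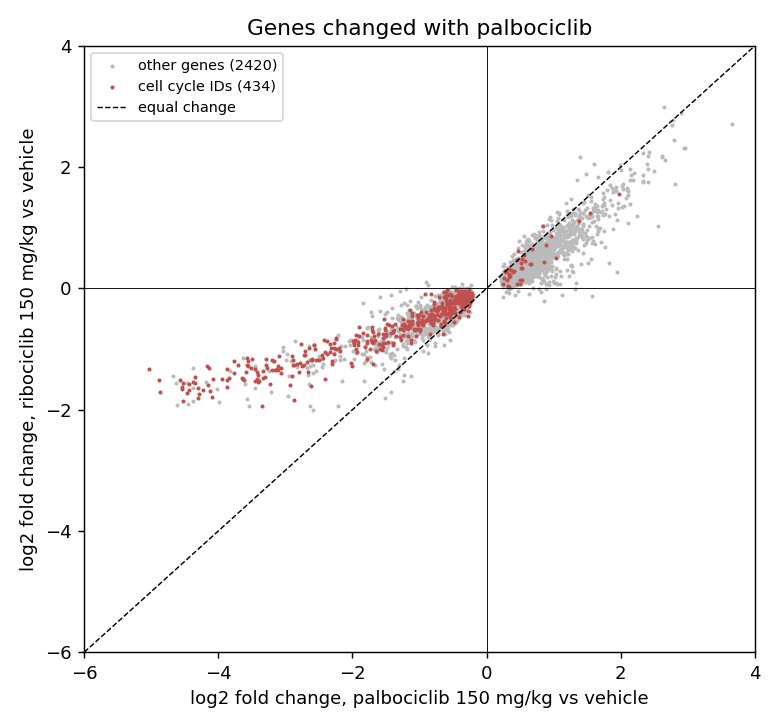
Log2 fold change against vehicle with palbociclib (horizontal) and ribociclib (vertical), both at 150 mg/kg, for the 2854 genes changed with palbociclib, with cell cycle IDs in red and equal change as a dashed line. The cell cycle genes with the largest palbociclib falls, with a median of -4.37, had a median of -1.61 with ribociclib.

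Abemaciclib and palbociclib at 150 mg/kg did not differ at any gene in edgeR or in DESeq2 (0 genes, with 638 below an unadjusted p of 0.05 in edgeR). With the first residual component as a covariate, a setting chosen after the data were examined, edgeR called 31 genes for abemaciclib 150 vs palbociclib 150, 29 higher and 2 lower with abemaciclib. The cell cycle score differed by 0.022 (95% interval -0.072 to 0.12, exact permutation test, p = 0.571, n = 3 and 5) and the G2/M-high score by 0.038 (-0.14 to 0.22, p = 0.643). The G1-high score differed by 0.038 (-0.034 to 0.11, exact permutation test, p = 0.268), and by 0.057 without palbociclib mouse 47, which had 1 tumour (exact permutation test, p = 0.0286, not adjusted). The S-high score differed by -0.0027 (-0.12 to 0.11, exact permutation test, p = 0.982). These intervals bound the difference and do not show that the drugs act alike. In counts simulated for this comparison, 97.6% of 4-fold, 81.1% of 2-fold and 27.8% of 1.5-fold changes were called.

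The 5 abemaciclib doses showed how the response grew. The cell cycle score was -0.061 ± 0.024 at 25 mg/kg, -0.23 ± 0.075 at 75, -0.38 ± 0.11 at 100, -0.45 ± 0.031 at 125 and -0.49 ± 0.017 at 150 (SD, n = 3 each). Over the 15 mice the score fell with log2 dose (Pearson r = -0.926, permutation p = 1e-05, the smallest that 100000 resamples can give; Spearman rho = -0.895, p = 4e-05; adjusted p = 1.33e-05 for r over 4 lists). Without the 3 mice at 25 mg/kg, which include those farthest from the median dose, r was -0.859 (permutation p = 0.00043). For the G2/M-high list r was -0.936 and -0.872 without those mice. In the abemaciclib dose trend, 625 genes fell and 175 rose with dose of 15102 tested (371 and 0 with spike-in scaling, 409 and 21 in left tumours alone), and 267 of the falling genes, 42.7%, were cell cycle IDs. Without the 25 mg/kg mice 129 genes passed, 125 of them falling, and without mouse 16 alone 528 passed. ENSG00000178999 and ENSG00000171848 both fell by 1.49 log2 units per doubling of the dose (SE 0.12 and 0.16). ENSG00000163141 rose by 0.30 per doubling (SE 0.065, edgeR adjusted p = 0.00563). ENSG00000105974 showed no trend (slope -0.049, SE 0.090, edgeR adjusted p = 0.801) and was 2.55-fold higher at 25 mg/kg (log2 1.35). Without mouse 16 that change was of like size (log2 1.21) but did not pass (edgeR adjusted p = 0.157).

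**Figure D3:**
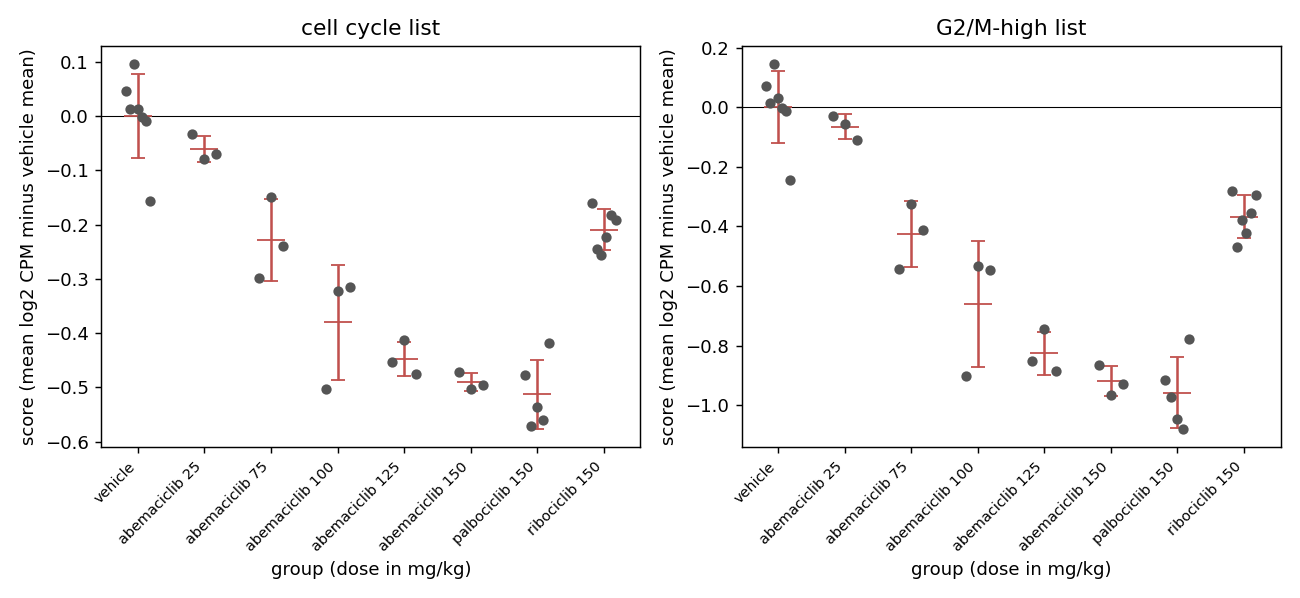
Cell cycle score (left) and G2/M-high score (right) in each mouse by group, as mean log2 CPM less the vehicle mean. Points are mice, and red bars are the mean ± SD. The abemaciclib means run from -0.061 at 25 mg/kg to -0.49 at 150 mg/kg, where palbociclib stands at -0.51 and ribociclib at -0.21.

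Against vehicle, abemaciclib changed 2546 genes at 125 mg/kg (1028 higher, 1518 lower), 1869 at 100 mg/kg (711 higher, 1158 lower) and 1928 at 75 mg/kg (797 higher, 1131 lower). Of the 1192 cell cycle genes, 369 fell at 125 mg/kg, 319 at 100 mg/kg and 275 at 75 mg/kg, while 37, 24 and 44 rose. Genes that fell at least 4-fold numbered 187, 138 and 45. All 4 lists were lower at each of these doses, also with an estimated correlation. With spike-in scaling the higher and lower counts were 119 and 335 for abemaciclib 125 vs vehicle, 18 and 335 for abemaciclib 100 vs vehicle, and 41 and 62 for abemaciclib 75 vs vehicle. The count at 125 mg/kg was 1428 or 1454 without mouse 30 or mouse 44. Without mouse 21 the count at 100 mg/kg was 1113. The count at 75 mg/kg was 888 or 938 without mouse 28 or mouse 29. In right tumours alone the counts were 1140 at 125 mg/kg, 814 at 100 mg/kg and 412 at 75 mg/kg. Left tumours alone gave 2959 at 75 mg/kg.

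At 25 mg/kg 208 genes changed, 129 higher and 79 lower. Among these 208, 18 cell cycle genes fell and 9 rose. With spike-in scaling, chosen after the data were examined, 0 genes passed (edgeR, 872 below an unadjusted p of 0.05). Right tumours alone gave 4. The G1-high list was lower (camera adjusted p = 0.000187, and adjusted p = 0.0465 with an estimated correlation), with 6 members lower and 2 higher, and its score was -0.13 ± 0.052 (exact permutation test, p = 0.025, adjusted p = 0.0303). That score did not pass without mouse 16, 32 or 33 (difference -0.15, -0.096 and -0.14, exact permutation p = 0.0556, 0.111 and 0.0556) or with the median over the list (-0.077, exact permutation p = 0.35). The S-high list was lower with the preset correlation (adjusted p = 0.000383) but not with an estimated one (adjusted p = 0.105), with 8 members lower and 1 higher. The whole cell cycle list behaved likewise (adjusted p = 0.00713, and adjusted p = 0.179 with an estimated correlation), and its score was not shown to differ from vehicle (exact permutation test, p = 0.233, 95% interval -0.17 to 0.048). This rests on vehicle mouse 45, without which the score differed by -0.087 (exact permutation test, p = 0.0119, not adjusted). The G2/M-high list did not pass (camera adjusted p = 0.166), and its score differed by -0.066 (-0.24 to 0.10), or by -0.11 without vehicle mouse 45 (exact permutation test, p = 0.0357, not adjusted). The S-high less G2/M-high score was not shown to differ from vehicle at this dose (exact permutation test, p = 0.5). It was higher than vehicle with the other treatments, by 0.41 with palbociclib (exact permutation test, adjusted p = 0.00884 over 7 tests), 0.11 with ribociclib (adjusted p = 0.0374) and 0.15, 0.21, 0.36 and 0.37 with abemaciclib at 75, 100, 125 and 150 mg/kg (adjusted p = 0.0233 at 75 and 0.0146 at the others). The count of 208 for abemaciclib 25 vs vehicle was 0 without mouse 16 (edgeR, 1414 below an unadjusted p of 0.05), 26 without mouse 32, 97 without vehicle mouse 20 and 118 without vehicle mouse 37, and with DESeq2 it was 592. The balance of directions depended on the method: DESeq2 called 249 higher and 343 lower, size factors by relative log expression gave 111 and 110, and the mouse as a random block over tumours in voom gave 276 and 357.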

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

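The test of total count below, and the bound used for a wrong label, were chosen after the results were seen. Vehicle mouse 45 stood apart from the other 6 vehicle mice, with a gap to the nearest of them larger than chance gives in about 1 of 20 such tests. Its cell cycle score was -0.157 (nearest other mouse -0.0095), its S-high score -0.119 and its G2/M-high score -0.246. Its spike-ins were 0.464% of counts (nearest other mouse 0.320%) and its scaling factor was 0.893 (nearest 0.985). These were the 5 values that stood apart among 27 tests, each of 1 measure in the vehicle, ribociclib or palbociclib group, and they are not independent of one another. The abemaciclib groups were not tested in this way.

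A failed library is argued against as the source, since both tumours of this mouse lay below the median of the other 12 vehicle tumours, by -0.143 and -0.172 against an SD of 0.060. Lower depth is argued against, since its total of 6491142 counts was above the vehicle median of 5727498. Whether it was a treated mouse with a vehicle label stays undecided. Its score on 298 genes raised by all 3 drugs, chosen without it, was 0.178. The lowest abemaciclib 25 mg/kg mouse had 0.503, and the other vehicle mice had an SD of 0.101. The condition set beforehand also asked that the score lie within the range of the other vehicle mice, and it did not (highest 0.090). Only a bound on the distance to the treated mice, chosen after the value was seen, argues against a wrong label. On 450 genes outside the cell cycle list that all 3 drugs lowered, its score was -0.090. The other vehicle mice lay above this (lowest -0.049) and the abemaciclib 25 mg/kg mice below it (highest -0.310). The cell cycle score of mouse 45, -0.157, lay below every abemaciclib 25 mg/kg mouse (lowest -0.079). No biological explanation was tested, and the make-up of its tumours, mouse cells included, stays open.

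Spike-ins, added RNA that entered no library size or test, made up 0.643% of counts in abemaciclib 100 mouse 21 and 0.589% in palbociclib mouse 36, above every vehicle mouse (highest 0.464%). No group was shown to differ from vehicle in its mean share (exact permutation tests, two-sided, lowest p = 0.379 of 7, adjusted p = 0.759).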

How the results depend on the processing

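Scaling by spike-ins, a residual component as a covariate, leaving out mice with 1 tumour, pooling abemaciclib doses and looser phase lists were chosen after seeing the data. No called direction of the 4 IDs against vehicle, the lists or the scores reversed, and other genes were not checked. For the 40 score tests, unadjusted, 474 alternatives kept their side of the threshold, 15 calls were lost and 3 gained. The gains were the G1-high score against palbociclib at 150 mg/kg (0.057 without palbociclib mouse 47) and, at 25 mg/kg without vehicle mouse 45, the cell cycle (-0.087) and G2/M-high (-0.11) scores. The losses were the cell cycle score at 75 mg/kg (-0.19 and -0.22 without mouse 28 or 34), and at 25 mg/kg the G1-high score (without mouse 16, 32 or 33, or with the median) and the S-high score (without mouse 16, 32 or 33 or vehicle mouse 18, 20, 25, 26 or 37, or with the median), where values ran from -0.15 to -0.077. For lists 129 kept their side and 3 calls were lost, all at 25 mg/kg: the cell cycle list with an estimated correlation (adjusted p = 0.179) and with fry (adjusted p = 0.0717), and the S-high list with an estimated correlation (adjusted p = 0.105). For the 4 IDs 639 kept their side, 25 calls were lost and 4 gained. The losses were 16 for ENSG00000105974, 8 for ENSG00000163141 and 1 for ENSG00000171848. Of these, 3 came from leaving out a mouse, for ENSG00000105974 without mouse 16 at 25 mg/kg (log2 1.21), 35 at 100 (0.75) and 46 at 150 (0.75), and the others from right or left tumours, glmTreat or spike-in scaling. No paired analysis was possible because mouse numbers are unique to a group. The symbol lists, cell type markers and mouse genes were not run.

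Counts of changed genes stayed within 1.5 times in 198 alternatives and moved further in 70. They are given in the order ribociclib 150 vs vehicle, palbociclib 150 vs vehicle, abemaciclib 150 vs vehicle, abemaciclib 125 vs vehicle, abemaciclib 100 vs vehicle, abemaciclib 75 vs vehicle, abemaciclib 25 vs vehicle, abemaciclib 150 vs ribociclib 150, palbociclib 150 vs ribociclib 150 and abemaciclib dose trend, with abemaciclib 150 vs palbociclib 150 apart. Fold changes tested against 1.5 by glmTreat, a stricter test, gave 137, 492, 450, 448, 350, 201, 0 (365 below an unadjusted p of 0.05), 121, 147 and 78. Spike-in scaling gave 237 (33 higher, 204 lower), 791 (113, 678), 521 (31, 490), 454 (119, 335), 353 (18, 335), 103 (41, 62), 0 (872 below an unadjusted p of 0.05), 105 (0, 105), 165 (1, 164) and 371 (0, 371). It put the median log2 change of all genes at -0.17 for palbociclib, -0.16, 0.24 and 0.15 for abemaciclib at 150, 75 and 25 mg/kg, -0.17 and -0.16 for abemaciclib and palbociclib against ribociclib, and -0.10 for the trend, and its directions are relative to those shifts. The residual component, which takes up spread between mice by construction, gave 3053, 4585, 3524, 4485, 3592, 4512, 2591, 469 and 1176 before the trend, and 31 for abemaciclib against palbociclib. That count was 0 in all other alternatives, DESeq2 and each mouse left out included, with 1375 below an unadjusted p of 0.05 when abemaciclib at 100, 125 and 150 mg/kg was pooled, and that pooling gave 461 against ribociclib.

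Single flanks have fewer counts per mouse. Right tumours gave 546 for ribociclib 150 vs vehicle, 965 for abemaciclib 150 vs vehicle, 1140 for abemaciclib 125 vs vehicle, 814 for abemaciclib 100 vs vehicle, 412 for abemaciclib 75 vs vehicle, 4 for abemaciclib 25 vs vehicle, 163 for abemaciclib 150 vs ribociclib 150 and 344 for the abemaciclib dose trend. Left tumours gave 2959 at 75 mg/kg, 180 for abemaciclib against ribociclib, 157 for palbociclib 150 vs ribociclib 150 and 430 for the trend, and the cause was not tested. Tumours as samples with the mouse ignored gave 2217 for ribociclib, 3002 at 75 mg/kg, 1024 at 25 mg/kg and 417 for abemaciclib against ribociclib, since tumours of 1 mouse then count as replicates. At 25 mg/kg the mouse as a random block gave 633 and DESeq2 592, and the cause was not tested. Only the groups compared, with fewer mice in the fit, gave 899 for ribociclib, 181 for abemaciclib against ribociclib and 213 for palbociclib against ribociclib. A mean count of at least 100, with fewer genes tested, gave 176 and 215 for the last 2. The trend gave 129 without the 25 mg/kg mice and 3630 on linear dose with vehicle at 0, which also takes in the difference from vehicle.

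With each mouse left out in turn, counts ran from 1129 to 1467 for ribociclib 150 vs vehicle and 2408 to 3454 for palbociclib 150 vs vehicle. They ran from 1161 to 2003 for abemaciclib 150 vs vehicle, 1428 to 2466 for abemaciclib 125 vs vehicle, 1113 to 1864 for abemaciclib 100 vs vehicle, 888 to 2270 for abemaciclib 75 vs vehicle and 0 to 218 for abemaciclib 25 vs vehicle. For abemaciclib 150 vs ribociclib 150 they ran from 166 to 283, for palbociclib against ribociclib 256 to 375, for the trend 528 to 980 and for abemaciclib against palbociclib 0 to 0. Moves beyond 1.5 times came at 25 mg/kg without mouse 16 (0, with 1414 below an unadjusted p of 0.05), mouse 32 (26), vehicle mouse 20 (97) and vehicle mouse 37 (118), and for the trend without mouse 16 (528). They also came without mouse 28 (888) or 29 (938) at 75 mg/kg, mouse 21 (1113) at 100, mouse 30 (1428) or 44 (1454) at 125, and mouse 43 (1175, and 173 against ribociclib) or 46 (1161, and 166) at 150. In simulated counts 58.2% of 1.5-fold changes were called for ribociclib against vehicle and 23.9% for abemaciclib at 25 mg/kg, so small changes are missed at this depth and number of mice.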

Other observations

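The tests of other splits of the mice, of a single mouse for ribociclib against palbociclib, of a cycling part of the cells and of the dose relation were chosen after the results were seen. Other splits of the same mice were refitted with only the groups compared, 60 per result with the real split included, or all 56 for abemaciclib against palbociclib. The number was raised after smaller draws had been seen, and in the largest of those no other split of palbociclib against ribociclib called a gene. The real count and the highest of the other splits were 899 and 313 for ribociclib against vehicle, 2046 and 265 for palbociclib, 1409 and 1 for abemaciclib at 150 mg/kg, 2054 and 0 at 125, 1283 and 0 at 100, 1473 and 2 at 75, and 207 and 105 at 25. They were 181 and 11 for abemaciclib against ribociclib, and 800 and 2 for the dose trend over 60 orders of the doses. In these 9 results only 1 of the splits drawn, the real one, gave as many genes. At 25 mg/kg the other split kept mouse 16 and called 105, and without that mouse the count was 0, so that result stays open. For palbociclib against ribociclib 2 of 60 splits gave at least the real 213, a share of 0.033, and the other split called 2550. That share lies below 0.05 among the splits drawn only. It does not exclude chance, since 60 splits do not bound the share over all possible ones. There were 462 possible splits for this comparison and 1716 for ribociclib against vehicle. Splits that mix the groups also carry the treatment difference as spread, which can lower their counts. For abemaciclib against palbociclib the real count was 0, which all 56 splits reach whatever the data, so the splits test nothing there, and another split called 617.

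Counts of 2550 and 617 point to a structure of the samples besides treatment. The split with 2550 genes set palbociclib mice 36, 40 and 41 with ribociclib mice 17 and 27, and the split with 617 set palbociclib mice 31 and 47 with abemaciclib 150 mouse 46. On the first component of the residuals, mice 36, 40, 41, 17 and 27 had values of 1.33, 0.33, 0.69, 1.48 and 1.28, and mice 31, 47 and 46 had -0.41, -1.93 and -0.61. The component does not part the first split fully, since ribociclib mouse 14, on its other side, had 0.77. Vehicle mouse 45 had the highest value, 2.86. The second principal component of all mice held 17.9% of the variance and did part the first split. Mice 36, 40, 41, 17 and 27 lay there between -42.8 and -19.1, and mouse 14 at -17.1. It did not part the second split, with mouse 31 at -8.50 and abemaciclib 150 mouse 43, on the other side, at 0.26. Mice 36, 40, 41, 17 and 27 had scaling factors of 0.946, 0.958, 0.941, 0.944 and 0.977, with mouse 14 at 0.961. The labels give no batch, and what these components stand for was not tested.

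Ribociclib lowered the cell cycle genes less than palbociclib at the same dose by weight. Depth is argued against, since thinning every mouse to 2672628 counts left a score difference of -0.267 (95% interval -0.33 to -0.20), and scaling is argued against, since the cell cycle genes less all other genes differed by -0.306 (-0.37 to -0.24). A single mouse is argued against, since the difference nearest 0 with 1 mouse left out was -0.288. A candidate explanation is that a part of the cells kept cycling: 32.9% unchanged cells with the rest at the palbociclib level, fitted on 397 lowered cell cycle genes, gave an error on 1108 other lowered genes of 0.849 times that of 1 slope on the log scale. The same ratio was 0.895 for abemaciclib at 25 mg/kg and 0.910 at 75 mg/kg, so the curvature is not particular to ribociclib, and exposure, potency and other curves that level off stay open. The 1108 other genes are only those outside the cell cycle list, which need not hold every cell cycle gene. They were chosen by the same palbociclib falls in the same mice, so the ratio is not an independent test of a cycling part.

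Genes raised by palbociclib reached a larger part of that response at 25 mg/kg abemaciclib than the lowered cell cycle genes did. Over the 1349 genes raised by palbociclib, the abemaciclib changes had slopes against the palbociclib changes of 0.54 at 25 mg/kg, 0.67 at 75, 0.82 at 100, 0.81 at 125 and 0.74 at 150. Over the 397 lowered cell cycle genes the slopes were 0.18, 0.52, 0.74, 0.94 and 1.02, and over the 1108 other lowered genes 0.28, 0.61, 0.80, 0.94 and 1.00. Ribociclib at 150 mg/kg gave a like order, with slopes of 0.71 for raised, 0.42 for lowered cell cycle and 0.50 for other lowered genes. With separate vehicle mice, its slope of raised genes less that of lowered cell cycle genes had a median of 0.15 (lowest -0.005). The order was thus also seen outside low-dose abemaciclib. Genes were chosen by their palbociclib change, which by itself lowers such slopes. With separate vehicle mice for each comparison, the median slopes of raised genes were 0.40 at 25 mg/kg and 0.60 at 150 mg/kg. Those fits also had fewer vehicle mice per comparison, so how much of the drop came from sharing was not tested.

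The difference at the lowest dose may reflect dose. Whether raised genes were nearer a ceiling than the cell cycle genes was not tested. The slope of raised genes less that of lowered cell cycle genes fell with log2 dose over the 15 abemaciclib mice (Pearson r = -0.886, permutation p = 1e-05, the smallest possible; Spearman rho = -0.949, p = 1e-05), and r was -0.857 (permutation p = 0.00042) without the 3 mice at 25 mg/kg. From 25 to 150 mg/kg the slope of lowered cell cycle genes rose from 0.18 to 1.02. That of raised genes went from 0.54 to 0.74. The correlation with dose therefore largely restates the cell cycle trend and does not test a ceiling of the raised genes. Shared vehicle mice are argued against as the whole source of the difference at 25 mg/kg. It had a median of 0.226 over 35 splits of the vehicle mice, with a lowest of 0.054. Among genes with palbociclib changes of 0.5 to 1 log2 unit the difference was 0.214, and in each of the 3 mice it was at least 0.207. These values used the vehicle mice shared with the palbociclib comparison, and separate vehicle mice were not tried for them. Sharing can add to the difference, and the 3 mice have the same baseline. The larger changes of cell cycle genes and a single mouse therefore stay undecided as sources. What the raised genes are stays open, since the files do not name them.

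Left and right tumours of the same mouse differed at 99 of 14147 genes, 46 higher and 53 lower on the right, and 2 of the lowered genes were cell cycle IDs (edgeR with the mouse as a block, 31 mice). No gene passed for a difference between treated and vehicle mice in this contrast (0 genes in edgeR, not run in another tool). Still, 3183 of the 14147 genes had an unadjusted edgeR p below 0.05, a larger share than the 0.05 that chance gives. A flank difference that depends on treatment is therefore not excluded, and the source of this excess was not tested.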
